A study of Homo sapiens with 302 samples.

How the data were processed

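The series holds 302 plasma samples with 1 peak list each, 240 from controlled and 62 from uncontrolled disease as the sample labels give them, with the library batch (6 batches) taken from the sample titles. Per the labels' protocols, cell-free DNA was extracted from plasma, ligated to sequencing adapters, glucosylated at 5hmC by β-glucosyltransferase with an azide-modified glucose, biotinylated by click chemistry, pulled down on streptavidin beads and amplified by PCR. Per the submitters' processing notes, the tools named are bcl2fastq, Trimmomatic 0.39, BWA 0.7.17-r1198, MACS2 2.2.7.1 and deepTools, and the genome build is hg38. Their settings are not given in the sources used here. The lists have the 10-column narrowPeak layout. They hold the authors' values for each peak: a score, the fold enrichment over background as a linear ratio, and the -log10 p and -log10 q of the peak. The deposited score was 10 times the -log10 q, and no listed peak had a q above about 0.05, so the lists hold peaks past that threshold only. Peaks were called for each sample on its own. No normalization between samples was part of the deposited values, and fold, p and q were used only to filter or rank peaks within a list and to describe it.

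Read totals are not in the lists. The fold of a peak equals its pileup plus 1 over the background pileup plus 1, and its p follows from a Poisson distribution with that background, so both pileups were solved from the deposited fold and -log10 p for 2000 peaks of each list. In every list all 2000 matched a whole-number pileup within 0.002 of the -log10 p, and the commonest background value was taken as the background pileup of the list. It stands for depth but is not a read count, and in the shallowest lists it is less certain.

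Autosomal peaks were kept, and sex chromosomes were left out. A minimum of 1000 autosomal peaks per sample removed no sample. Protein-coding genes of the RefSeq table for GRCh38.p14, the same build as hg38, gave gene starts and ends. The table holds no strand, exons or transcription start sites, so the planned split into promoters, exons, introns and intergenic sequence was replaced by 3 classes of peak midpoints: within 1 kb of either end of a gene, elsewhere inside a gene, and outside genes. Peaks overlapping a gene by at least 1 bp were counted per sample and gene. Genes with a peak in at least 10% of samples (16379) were tested with limma 3.58.1 in R 4.3.3 on log2(peaks + 1), with trend and robust variance, batch as a factor and a natural spline of log10 peak number with 3 degrees of freedom. A fold on this scale understates the change of genes with few peaks. Differences are uncontrolled minus controlled, and Benjamini-Hochberg adjusted p below 0.05 was the threshold. Gene lists were tested on the same fit with camera at a preset correlation of 0.01, two-sided, with an estimated correlation as the alternative and fry beside it. The 24 lists were fixed before the data were examined: alveolar epithelium and lung adenocarcinoma, airway epithelium, EGFR family and bypass receptor tyrosine kinases, RAS-MAPK and PI3K signalling, cell cycle and proliferation, epithelial-mesenchymal transition and matrix, squamous epithelium, neuroendocrine and neuronal, hepatocytes, neutrophils, monocytes and macrophages, T and NK lymphocytes, B lymphocytes and plasma cells, erythroid, megakaryocytes and platelets, endothelium, cardiac and skeletal muscle, bone and stroma, interferon response and antigen presentation, hypoxia and glycolysis, WNT, NOTCH and Hedgehog signalling, developmental transcription factors, DNA methylation and hydroxymethylation enzymes, and lung cancer tumour suppressors and DNA repair.

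Named genes followed a rule set at the same time. It takes the 12 largest rises and the 12 largest falls among genes past the threshold with the same sign in at least 4 of the 5 batches with more than 1 uncontrolled sample, all of them if fewer pass, and the 10 smallest p-values if none pass. It adds 4 members of each list that passes, the member with the smallest p of every other list, and EGFR, MET, ERBB2, NKX2-1, SFTPC, ALB and TET2 where tested. Genes named outside the rule are said to be.

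Peak number, covered length, median peak width, median fold and background pileup were compared by permutation tests of the batch-adjusted difference, with 100000 permutations of the labels within batches, two-sided. Shares of peaks by genomic class and by chromosome were tested in the same way after regression on batch and the spline. Presence of a peak in autosomal windows of 10 kb, for windows with a peak in 10% to 90% of samples, was tested with limma and the same covariates. The classifier was a ridge logistic regression (scikit-learn 1.9.0) on the gene matrix with batch and spline regressed out without use of the labels, trained on 5 batches with the penalty chosen by 5-fold cross-validation, scored in the batch left out and averaged over batches by their number of pairs, with 100 permutations of the labels. Gene counts were recomputed for 99 other splits of the samples within batches and window counts for 49. The permutation test, the limma fit, the classifier and the spread of list means were checked on simulated data with known changes.

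Peak density in the gene lists was set against 10000 random lists matched on gene length. This description, the tests of peak width and background pileup, and most tests of the closing observations were added after the data were examined. The computations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Alternatives covered a minimum of 10000 peaks per sample, each batch left out, peaks with q of at most 1e-04, the 10000 best peaks of each of the 253 samples that have as many (fitted on batch without the spline), presence or covered share in place of counts, a pseudocount of 0.5, no filter on genes, no spline, sample weights, 50 kb windows, 2 kb around gene ends and other inputs and folds for the classifier. No pair of lists was alike enough to be 1 library deposited more than once.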

Results

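Plasma cell-free DNA from patients with EGFR-mutant non-small cell lung cancer was profiled for 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine that TET enzymes make and that marks active genes and enhancers. DNA fragments carrying 5hmC were tagged with an azide-modified glucose, biotinylated, captured on streptavidin beads and sequenced, and each sample is represented by 1 list of enriched regions (peaks). Of the 302 samples, 240 came from disease that was controlled, where treatment was not switched within 30 days of the blood draw, and 62 from disease that was uncontrolled, meaning untreated or needing a change of therapy in that time. The libraries were made in 6 batches, which held 9 uncontrolled and 26 controlled samples, 10 and 28, 16 and 24, 1 and 19, 15 and 62, and 11 and 81. The lists held between 2483 and 407439 autosomal peaks, with a median of 80502.5. Read totals are not part of the lists, but the background pileup behind each list, the mean number of fragments over a base that the peak caller used as its null, could be recovered from the peak statistics and ran from 0.05 to 3.72 with a median of 0.923. The labels do not tie samples to patients, so samples were treated as independent and p-values may be too small where 1 patient gave several samples.

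In both groups the peaks were dense in genes of megakaryocytes and endothelium and sparse in developmental, hepatocyte and neuronal genes. Genes of megakaryocytes and platelets held 9.19 ± 2.08 peaks per 100 kb of gene per 100000 autosomal peaks (SD, n = 302), against a median of 4.81 in random lists of genes of the same lengths, and 9988 of 10000 random lists lay lower. Endothelial genes held 7.86 ± 1.63, above 9799. Erythroid genes held 8.73 ± 2.65, above 9924 random lists, but 7.56 ± 1.71, above 8815, without RHD and RHCE, a near-identical pair where the position of reads is uncertain. Without PF4, SLC2A3 or SDHA, which also have close copies elsewhere, the lists of megakaryocytes and platelets, of hypoxia and glycolysis and of DNA methylation and hydroxymethylation enzymes still lay above 9993, 9936 and 9866 random lists. Among megakaryocyte, platelet and endothelial genes, TUBB1, the platelet beta-tubulin on chromosome 20 from 59016438 to 59026654, carried a peak in 73.5% of the 302 samples, TGFB1 in 81.1% and PECAM1, the endothelial adhesion molecule CD31, in 87.4%. RAS-MAPK and PI3K signalling genes held 8.22 ± 1.2 (above 9996 random lists), genes of hypoxia and glycolysis 8.96 ± 1.92 (above 9949) and the list of DNA methylation and hydroxymethylation enzymes, which also holds the metabolic enzymes IDH2 and SDHA as its densest members, 8.75 ± 1.95 (above 9943). Neutrophil genes, with 8.81 ± 3.11, lay above 9305 random lists, monocyte and macrophage genes above 2402 and T and NK lymphocyte genes above 1178. The opposite end held developmental transcription factors, at 1.67 ± 0.751 peaks per 100 kb against 6.93 in random lists, with 0 of 10000 random lists lower. No sample had a peak in NKX2-1, the lineage factor of lung adenocarcinoma, in the homeobox genes OTX2 and ISL1, or in HOXC10. Hepatocyte genes held 3.67 ± 1.53 (9 random lists lower), and ALB, which encodes albumin, had a peak in 2.98% of samples. Neuroendocrine and neuronal genes held 1.24 ± 0.523 (1.17% of random lists lower). The remaining 12 lists lay above between 299 random lists, for airway epithelium, and 9520, for interferon response and antigen presentation, and the alveolar list lay above 398. These values describe the lists across genes, which are not independent replicates, and the example genes were picked after their values were seen.

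**Figure D1:**
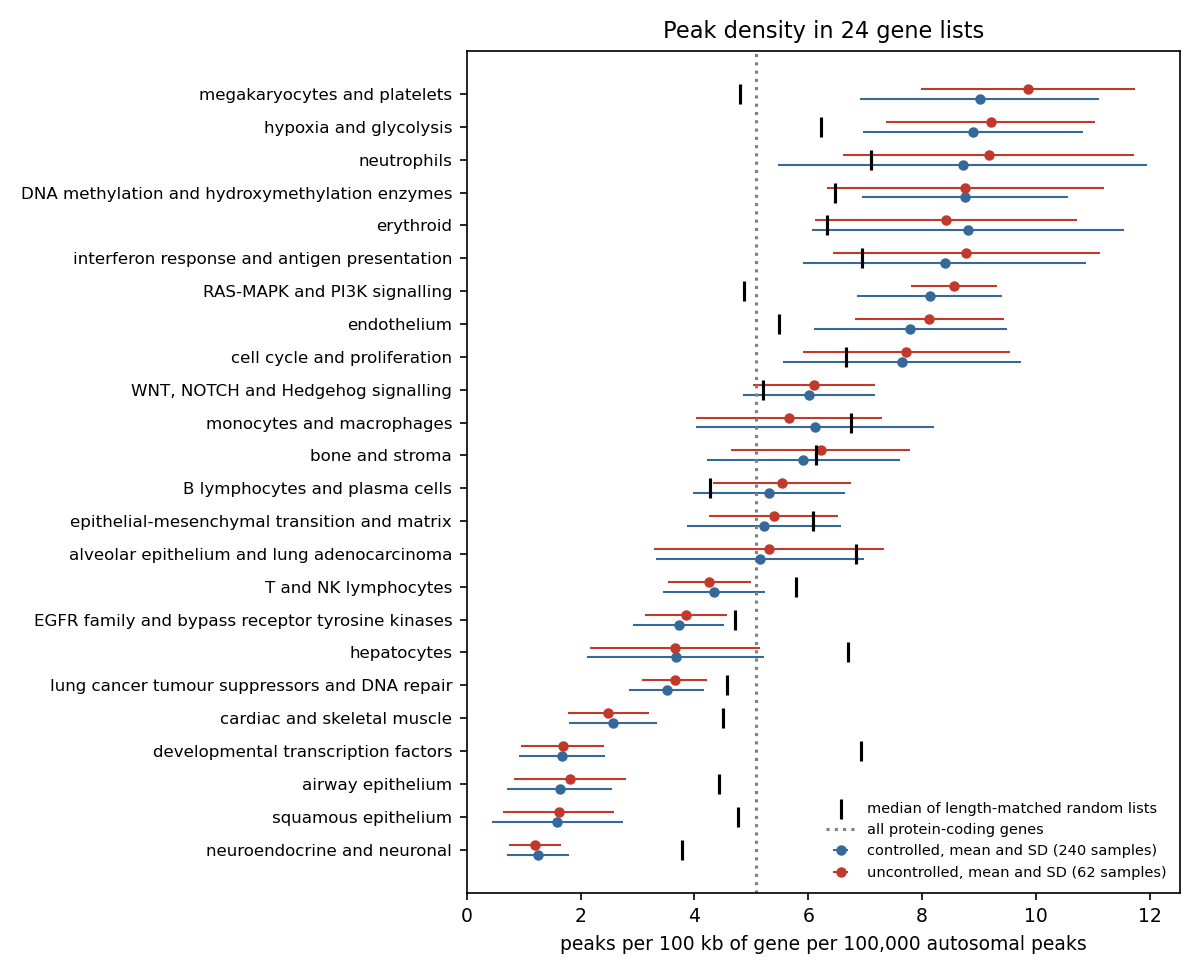
Peak density in the 24 gene lists, in peaks per 100 kb of gene per 100000 autosomal peaks. Points are means over the 240 controlled and the 62 uncontrolled samples with SD bars, ticks are the medians of length-matched random lists, and the dotted line is the mean over all protein-coding genes (5.08). Megakaryocyte and platelet genes lie highest at 9.19 over all samples, and neuroendocrine and neuronal genes lowest at 1.24.

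Uncontrolled and controlled disease were first compared for how many 5hmC peaks a sample had. The number did not differ beyond its error. The batch-adjusted ratio of uncontrolled to controlled was 1.17 (95% interval 0.909 to 1.5, permutation p = 0.233, two-sided, labels permuted within batch). Within batches 1 to 6 the difference in mean log10 peak number was -0.041, 0.33, -0.082, -0.014, 0.133 and 0.012, and batch 4 held only 1 uncontrolled sample. The median peak width was 12.1 bp greater in uncontrolled disease (SE 5.66, p = 0.0365), and the background pileup was 1.2 times as high (95% interval 1.03 to 1.4, p = 0.0179). Neither passed adjustment over the 5 list measures compared (adjusted p = 0.0912 and 0.0895), nor did covered length (ratio 1.23, p = 0.146) or median fold enrichment (-0.065, SE 0.0375, p = 0.0895). The width difference by batch was 30.6, 33.4, 7.65, -18.7, 9.33 and -5.82 bp, and that of log10 background pileup was 0.0133, 0.255, 0.0207, -0.028, 0.0765 and 0.0674. Given the background pileup, the sign of the difference in peak number turned, to a ratio of 0.888 (p = 0.0382).

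**Figure D2:**
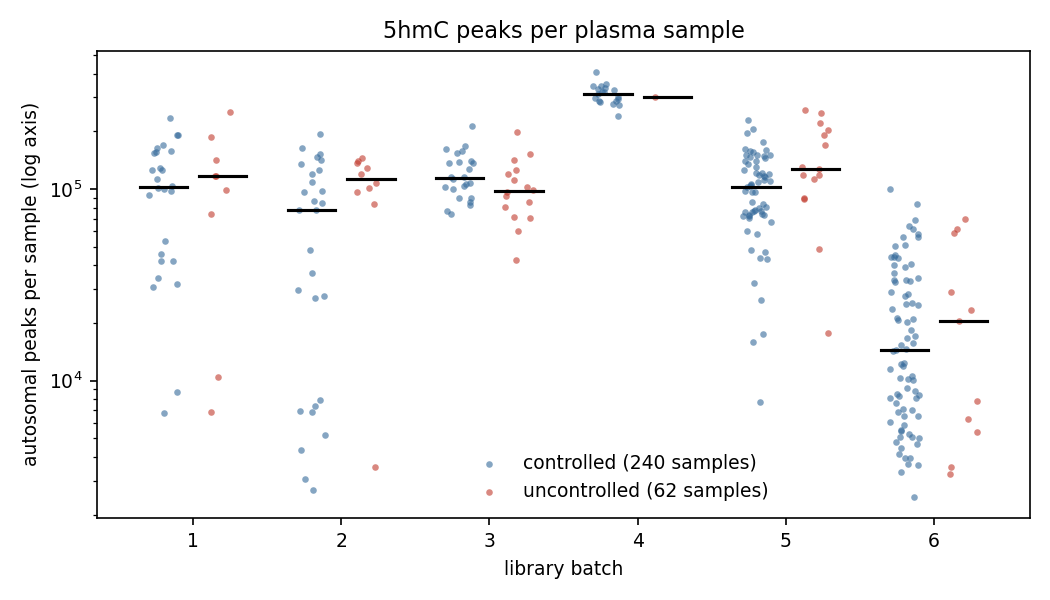
Autosomal 5hmC peaks per sample on a log axis, by library batch, for 240 controlled and 62 uncontrolled samples. Each point is 1 sample and black lines are medians. Batch 6 has medians of 14523 and 20363 peaks and batch 4 of 312886 and 300758, for controlled and uncontrolled samples, while the groups overlap within every batch that holds more than 1 uncontrolled sample.

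The next comparison asked which genes carried more or fewer 5hmC peaks in uncontrolled disease. Of 16379 protein-coding genes tested, 2 rose and 1 fell. EIF2B1, which encodes the alpha subunit of the translation initiation factor eIF2B (chromosome 12, 123620406 to 123633686, hg38), had a peak in 54.8% of uncontrolled and 22.9% of controlled samples. Its log2(peaks + 1) was 0.32 higher (SE 0.0622, limma adjusted p = 0.00731). RNF207, a RING finger gene on chromosome 1 (6206119 to 6221299), had a peak in 59.7% against 30% of samples and was 0.31 higher (SE 0.0667, limma adjusted p = 0.0296). FBXO16, an F-box gene on chromosome 8 (28428412 to 28490229), held 2.31 ± 2.26 peaks (SD, n = 62) against 2.78 ± 2.92 (n = 240) and was lower by a log2 difference of -0.35 after adjustment (SE 0.0761, limma adjusted p = 0.0296). The share of samples with a peak in FBXO16 ran the other way, 75.8% against 73.3%, and its difference was -0.18 without the spline of peak number (limma adjusted p = 0.379) and -0.076 for presence of a peak (limma adjusted p = 1). By batch, the adjusted difference of EIF2B1 was 0.596, 0.528, 0.138, -0.42, 0.36 and 0.151, that of RNF207 was 0.286, 0.596, 0.341, 0.668, 0.157 and 0.203, and that of FBXO16 was -0.122, -0.359, -0.643, -0.298, -0.529 and 0.0287. EIF2B1 shares 538 bp with DDX55, and RNF207 overlaps the end of ICMT, so a peak there counts for both genes. The 10 kb windows with the smallest p in each gene, from 123630001 to 123640000 and from 6210001 to 6220000, hold neither overlap, although no window passed. The first also holds part of GTF2H3, which lies from 123633829. With batch 1 or batch 2 left out 0 genes passed, and with batches 3 to 6 left out 1 or 2 did. At an unadjusted p below 0.05 there were 867 genes (5.29%), 507 higher and 360 lower. In simulated changes of 200 genes with a mean of at least 1 peak, 71% of 1.5-fold and 96.3% of 2-fold changes in peak number were recovered, with a mean of 12.8 and 14.4 unchanged genes called beside them. Of the smallest changes simulated, with a median estimate of 0.19 on the log2(peaks + 1) scale, 18.2% were recovered, so most changes of that size would be missed. A mean of 3 unchanged genes were called beside them. EIF2B1 (mean 0.69 peaks in uncontrolled and 0.33 in controlled samples) and RNF207 (0.9 and 0.475) held fewer than 1 peak on average. The simulated changes therefore do not describe such genes.

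**Figure D3:**
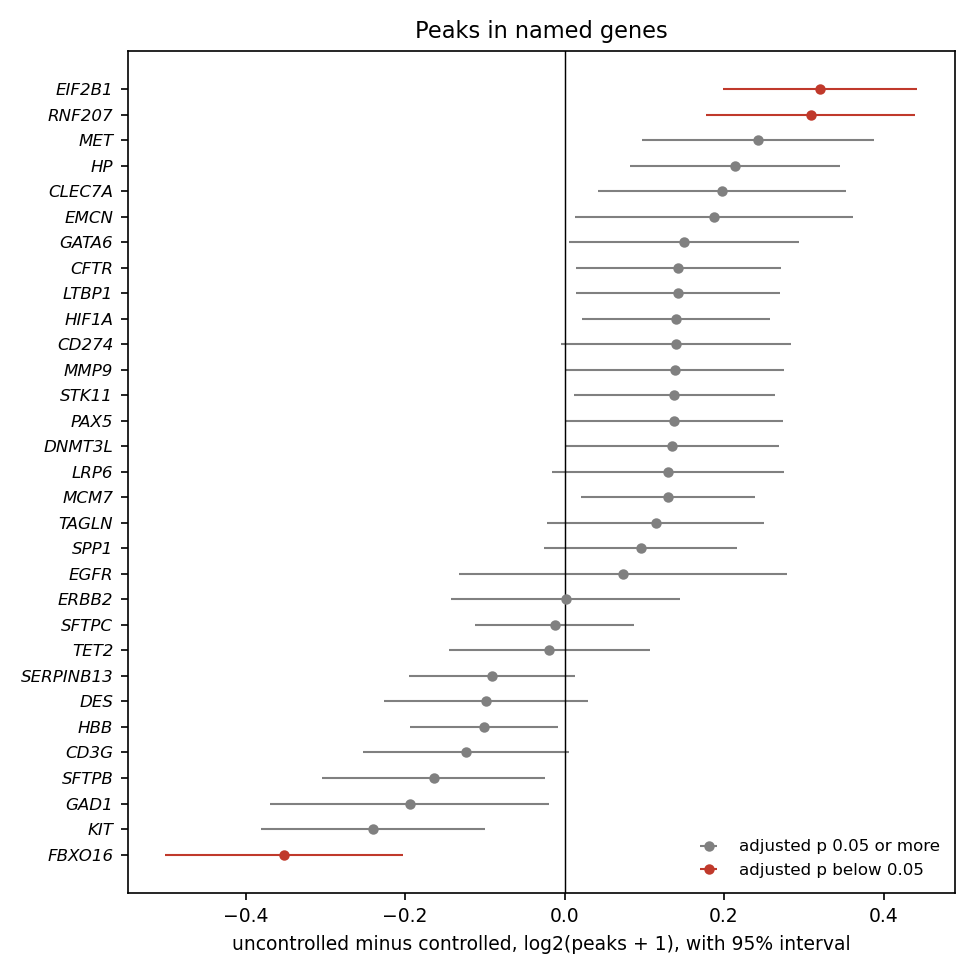
Difference between uncontrolled and controlled disease in log2(peaks + 1) for the 31 named genes, after adjustment for batch and peak number. Points are limma estimates with 95% intervals. EIF2B1 (0.32), RNF207 (0.31) and FBXO16 (-0.35) pass the adjusted threshold and the other genes do not.

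None of the 24 gene lists fixed before the data were examined passed as a set (camera with a preset correlation, adjusted over the lists), and none did with an estimated correlation. Among the lists closest to the tumour, the EGFR family and bypass receptor tyrosine kinases had 13 of 25 tested members higher (camera p = 0.788). MET, the receptor of hepatocyte growth factor whose amplification is a known route of resistance to EGFR inhibitors, had a log2 difference of 0.24 (SE 0.0743, limma adjusted p = 0.545), with values of 0.112, 0.372, 0.377, 0.0616, 0.105 and 0.27 in batches 1 to 6. KIT, the stem cell factor receptor, had -0.24 (SE 0.0718, limma adjusted p = 0.545). The size of the KIT difference rests on the adjustment for peak number, since its mean was 5.02 peaks in uncontrolled and 4.92 in controlled samples, and its difference was -0.03 without the spline. It was 0.049 with the 10000 best peaks of the 253 samples that have as many, fitted on batch alone. These 2 genes passed when adjusted over the list alone and not over all genes, although MET also passed over all genes when the covered share of the gene was tested in place of the number of peaks (adjusted p = 0.0331). EGFR itself, on chromosome 7 from 55019017 to 55211628, held 10.3 ± 10.2 peaks in uncontrolled and 7.92 ± 9.58 in controlled samples, a log2 difference of 0.07 after adjustment (SE 0.105). The difference of ERBB2 was 0.0013 (SE 0.0731). The alveolar and lung adenocarcinoma list had 11 of 25 members higher (p = 0.39), with a difference of -0.16 for the surfactant gene SFTPB (SE 0.0714) and of -0.012 for SFTPC (SE 0.051). NKX2-1, with 0 peaks in both groups, was not tested. In airway epithelium 8 of 16 members were higher (p = 0.727, CFTR 0.14), in squamous epithelium 8 of 10 (p = 0.602, SERPINB13 -0.091) and among neuroendocrine and neuronal genes 4 of 14 (p = 0.0261, adjusted p = 0.313, GAD1 -0.19).

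The tumour suppressor and DNA repair list had 17 of 27 members higher, led by STK11, the kinase LKB1, with 0.14 (SE 0.0644). Its set test gave p = 0.0581, adjusted p = 0.358. STK11 also led RAS-MAPK and PI3K signalling, where 23 of 32 members were higher (p = 0.335). Cell cycle and proliferation had 13 of 30 higher (p = 0.322), with 0.13 for the replication helicase subunit MCM7. Epithelial-mesenchymal transition and matrix had 13 of 26 (p = 0.733, TAGLN 0.11), hypoxia and glycolysis 13 of 23 (p = 0.0896, HIF1A 0.14), and WNT, NOTCH and Hedgehog signalling 14 of 32 (p = 0.929, LRP6 0.13). Developmental transcription factors had 6 of 18 higher (p = 0.0843, GATA6 0.15). In the list of DNA methylation and hydroxymethylation enzymes 11 of 22 were higher (p = 0.975), with 0.14 for DNMT3L and -0.019 for TET2 (SE 0.0642), which encodes a 5hmC-forming dioxygenase. TET2 held 13.2 ± 8.7 peaks in uncontrolled and 11.7 ± 10.9 in controlled samples. Interferon response and antigen presentation had 16 of 35 higher (p = 0.867), with 0.14 for CD274, which encodes PD-L1.

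Of the lists for blood and normal tissue, T and NK lymphocytes had the smallest p, with 13 of 38 members higher (camera p = 0.00758, adjusted p = 0.182) and a mean log2 difference of -0.031. Within batches 1 to 6 this mean was -0.036, 0.0307, -0.068, 0.0482, -0.05 and -0.02, and with batch 2 left out the list passed (adjusted p = 0.0345). It kept the smallest p with some other batches left out and lost it with others. With background pileup and peak width as covariates neutrophils came first (camera p = 0.0504), so the p of T and NK lymphocytes was no smaller. With the 10000 best peaks per sample, fitted on batch alone, DNA methylation and hydroxymethylation enzymes came first (camera p = 0.0552). The T and NK member with the smallest p was CD3G, a chain of the T cell receptor complex, with -0.12 (SE 0.0661). Monocytes and macrophages had 8 of 23 higher (p = 0.118, CLEC7A 0.2), B lymphocytes and plasma cells 10 of 25 (p = 0.255, PAX5 0.14), neutrophils 10 of 27 (p = 0.391, MMP9 0.14) and erythroid genes 10 of 28 (p = 0.0768, HBB -0.1). Megakaryocytes and platelets had 13 of 26 higher (p = 0.931, LTBP1 0.14) and endothelium 12 of 26 (p = 0.655, EMCN 0.19). Hepatocytes had 15 of 28 higher (p = 0.616). HP, which encodes haptoglobin, an acute-phase protein of the liver, had a peak in 54.8% of uncontrolled and 32.1% of controlled samples and a difference of 0.21 (SE 0.0671, limma adjusted p = 0.565), and was the only gene of that list to pass when adjusted over the list alone. ALB, with a peak in 3.23% and 2.92% of samples, was not tested. Cardiac and skeletal muscle had 3 of 14 higher (p = 0.138, DES -0.098) and bone and stroma 8 of 17 (p = 0.899, SPP1 0.095). In the 22 lists other than the receptor kinases and hepatocytes, 0 members passed when adjusted over the list alone.

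Peaks lay in the same parts of the genome in both groups within error. Peaks inside protein-coding genes and more than 1 kb from a gene end made up 59 ± 3.14% of autosomal peaks in uncontrolled samples (SD, n = 62) and 57.9 ± 3.94% in controlled samples (n = 240), a difference of 0.361 points after adjustment for batch and peak number (SE 0.258, permutation p = 0.136). By batch it was 0.617, -0.469, 0.0806, 0.943, 0.285 and 1.1 points. Within 1 kb of a gene end lay 5.23 ± 0.767% and 5.22 ± 0.751% (p = 0.315), and outside genes 35.7 ± 3.21% and 36.9 ± 4.15% (p = 0.126). The adjusted p of the 3 shares ran from 0.203 to 0.315.

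Copy number changes of tumour DNA, where many patients share them, could move the peak shares of whole chromosomes. In a comparison of group means, 0 of the 22 autosomes passed. Changes that differ between patients could cancel in such a comparison. Chromosome 1 had the smallest p, with 9.91 ± 0.221% of peaks in uncontrolled and 9.85 ± 0.249% in controlled samples, a log2 difference of 0.011 (SE 0.005, permutation p = 0.0191, adjusted p = 0.341). Chromosome 7, which holds EGFR and MET, had an adjusted log2 difference of 0.02 (SE 0.0115, p = 0.0727) with unadjusted means of 5.81 ± 0.846% and 5.91 ± 0.909%, and chromosome 15 had -0.022 (SE 0.0115, p = 0.031). Which chromosome came first depended on the setting. In samples with at least 10000 peaks chromosome 1 had a log2 difference of 0.0052 (p = 0.155) and chromosome 7 the smallest p (0.021, p = 0.012, adjusted p = 0.264), as it did with background pileup and peak width as covariates, a setting added after the data were examined (0.028, p = 0.00704, adjusted p = 0.155). With the 10000 best peaks of the 253 samples that have as many, fitted on batch alone, chromosome 21 came first (-0.051, p = 0.0201, adjusted p = 0.442) and chromosome 7 had p = 0.0729.

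**Figure D4:**
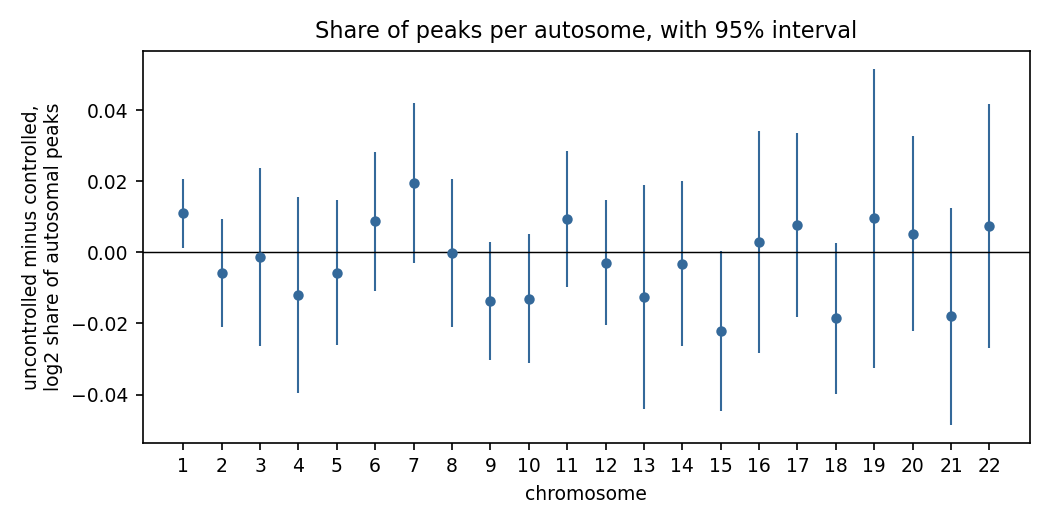
Log2 difference between uncontrolled and controlled disease in the share of autosomal peaks on each of the 22 autosomes, after adjustment for batch and peak number. Points are estimates with 95% intervals, over 62 and 240 samples. Chromosome 1 lies at 0.011 and chromosome 15 at -0.022, and none passes adjustment.

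Sequence outside genes was covered by a test of 142153 autosomal windows of 10 kb. None passed in limma, and 8525 had an unadjusted p below 0.05. The smallest p belonged to chromosome 12 from 123630001 to 123640000, which holds parts of EIF2B1 and of GTF2H3, a subunit gene of the transcription factor TFIIH. A peak lay there in 54.8% of uncontrolled and 24.6% of controlled samples (difference 26.5 points after adjustment, SE 5.53, limma adjusted p = 0.272). The next were windows in SVIP on chromosome 11 (33.9% and 12.5%, limma adjusted p = 0.375) and NOL4L on chromosome 20 (75.8% and 44.2%, limma adjusted p = 0.375). These windows were named after their values were seen.

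The title of the series asks whether 5hmC profiles tell the disease states apart. A ridge logistic regression on the peaks of all 16379 genes, trained on 5 batches and scored in the batch left out, gave an area under the ROC curve of 0.522, against a median of 0.506 and a highest value of 0.626 over 100 permutations of the labels within batches (p = 0.386, one-sided). By batch the area was 0.462, 0.568, 0.549, 0.947, 0.649 and 0.37, and that of batch 4 rests on 1 uncontrolled sample. The number of peaks alone gave 0.557 (permutation p = 0.129). In separate runs on the same matrix with labels permuted within batches, the area was 0.533 with no shift planted, and 0.678 and 0.983 with shifts of 0.2 and 0.5 SD planted in 200 genes. Each area is from a single run. The SD was that of log2(peaks + 1) over all samples, before batch and peak number were regressed out. The runs therefore do not show that a shift of 0.2 SD on the adjusted scale would be found. The classifier used counts of called peaks and not read counts, so weak differences in signal within shared peaks would be missed.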

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

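The tests of peak width and background pileup, and those that used these as covariates or as classifier inputs, were chosen after the results were seen, and the other alternatives were fixed before. The list lengths, which may follow depth, limit all values here. The number of genes past the threshold was small under every alternative tried and the genes were not stable. Against 2 higher and 1 lower gene, there were 4 higher and 1 lower in samples with at least 10000 peaks. Leaving out batch 1 or batch 2 gave 0 and 0, batch 3 gave 2 and 0, batch 4 or batch 5 gave 1 and 0, and batch 6 gave 0 and 1. Without the spline of peak number there were 6 and 0 (2379 genes at an unadjusted p below 0.05, against 867), with the covered share of the gene 9 and 0, with presence of a peak, stricter peaks (q at most 1e-04), a pseudocount of 0.5 or background pileup and peak width as covariates 1 and 0 each (with stricter peaks none of the 3 reported genes, with the others EIF2B1), and with sample weights or the 10000 best peaks per sample 0 and 0 (848 and 451 genes at an unadjusted p below 0.05 in limma). The 10000 best peaks, which only 253 samples have and which were fitted on batch alone, left 9977 genes to test. FBXO16 was among them. EIF2B1 and RNF207 had such a peak in too few samples and could not be called there. Counting a peak only with at least 0.5 of its length in the gene, or all genes without a filter, gave 2 and 1. EIF2B1 passed in 10 of 16 alternatives (adjusted p 0.000674 to 0.243), RNF207 in 5 of 16 (0.00424 to 0.757) and FBXO16 in 4 of 17 (0.00419 to 1), and none of the 3 changed sign. Over the 31 named genes, 24 of 506 values under alternatives changed sign, in 9 genes, none of them past the threshold, and of the 28 genes that did not pass only MET did so, with the covered share (adjusted p = 0.0331).

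1 gene list passed with batch 2 left out (T and NK lymphocytes, lower, adjusted p = 0.0345), and 0 did under the other alternatives. No genomic class, chromosome or window passed under any alternative tried. The area under the curve of the classifier lay between 0.472 and 0.573 over its alternatives, on both sides of 0.5, and none of these passed. The difference in log10 peak number stayed uncalled and above 0 with each batch left out, in longer lists, with stricter peaks and as covered length, but fell from 0.0666 to 0.0167 without batch 2 (p = 0.746) and became -0.052 (p = 0.0382) with the background pileup as a covariate. The difference in median width no longer passed an unadjusted 0.05 in samples with at least 10000 peaks (10.8 bp), without batch 1 (9.01 bp), batch 2 (8.12 bp), batch 3 (13.3 bp) or batch 5 (13.1 bp), or given the background pileup (1.7 bp). That of log10 background pileup did not without batch 2 (0.0471) or batch 5 (0.0815). The cause was not tested for these changes except where the alternative has fewer samples or genes.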

Other observations

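The tests of the spread of list means, of components, of peak width, fold and pileup as covariates, of width given depth and of batch 2 were chosen after related results were seen. The regroupings, the classifier and the fit with stricter peaks were planned, but what each would show was written down after, and the tests of neighbouring genes, of list means against disease state and of chromosome-scale spread were set out before their results were seen. Between samples, beyond batch and peak number, genes of myeloid cells and of platelets moved together. The mean of the 27 tested neutrophil genes had an SD between samples 1.64 times the median of 10000 random lists matched on gene length and on how often a gene has a peak, and 0 of the random lists were as high. This held in each of the 6 batches at a share under 5% of random lists. Megakaryocyte and platelet genes had a ratio of 1.4 with 0 random lists as high (5 of 6 batches), endothelial genes 1.27 with 1 (4 of 6), and monocyte and macrophage genes 1.23 with 5 (only 2 of 6). Hepatocyte genes had 1.19 with 26 random lists as high, erythroid genes 1.18 with 23, developmental transcription factors 1.18 with 22, receptor tyrosine kinases 1.17 with 27 and neuroendocrine and neuronal genes 1.16 with 45. With 1 member kept per Mb, to thin out neighbouring genes, developmental transcription factors fell to a ratio of 1.06 with 1234 random lists as high. That list then no longer stood apart. The ratio was 1.21 for hepatocyte, 1.14 for erythroid, 1.14 for receptor tyrosine kinase and 1.16 for neuroendocrine and neuronal genes. Before that thinning, 14 of the 24 lists exceeded random lists at an adjusted p below 0.05. Shared movement was thus not particular to blood lineages, although it was greatest in neutrophil and megakaryocyte genes. Alveolar and lung adenocarcinoma genes, with 1856 random lists as high, and airway genes, with 4350, did not stand apart.

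Blood lineages also had the largest shares at 1 end of the first 2 principal components of the gene matrix, among other lists. The first took 2.88% of the variance and had 9 of 27 neutrophil genes among the 5% of genes at one end, where chance gives 1.35, with FFAR2, a neutrophil receptor for short-chain fatty acids, and S100A12, a calcium-binding protein of neutrophil granulocytes, in front. The same end held 5 of 32 RAS-MAPK and PI3K genes and 5 of 27 tumour suppressor and DNA repair genes, where chance gives 1.6 and 1.35. The latter list was split, with 4 members at the opposite end. NEGR1, PCDH9 and NLGN1, neuronal adhesion genes, stood at the other end. The second took 2.48% and had 10 of 26 megakaryocyte and platelet genes, 8 of 28 erythroid and 8 of 26 endothelial genes at one end, where chance gives 1.3, 1.4 and 1.3, led by LRRC32, which anchors latent TGF-beta on platelets and regulatory T cells. That end also held 5 of 32 WNT, NOTCH and Hedgehog genes, and 5 of 23 monocyte and macrophage genes stood at the opposite end (chance 1.6 and 1.15). Scores on these components did not differ detectably between disease states (permutation p = 0.415 and 0.876). Of the first 5 components, the fourth had the smallest p (uncontrolled higher by 0.392 SD, SE 0.149, p = 0.012, adjusted p = 0.06). At its low end, among 5% of genes, stood 11 of 38 T and NK lymphocyte genes, 5 of 25 alveolar, 4 of 23 monocyte and macrophage, 4 of 25 B lymphocyte and plasma cell and 4 of 32 WNT, NOTCH and Hedgehog genes, where chance gives 1.9 for the first and 1.6 or fewer for the others, and uncontrolled samples scored away from that end. The high end held 4 of 27 tumour suppressor and DNA repair genes and 3 of 26 megakaryocyte and platelet genes (chance 1.35 and 1.3).

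The shared movement of neutrophil genes may reflect how much of the plasma DNA each sample drew from that lineage. This is a hypothesis from the same data. With peak width, fold and background pileup as covariates, the ratio was 1.65 for neutrophils and 1.34 for megakaryocytes and platelets, with 0 random lists as high for both. The spread thus stayed after adjustment for list quality as far as these capture it. The prediction for this was written after the results were seen and so carries no weight. For neutrophil and for megakaryocyte and platelet genes, neighbouring genes that share peaks were argued against, since with 1 member kept per Mb the ratios were 1.45 and 1.39. Disease state was argued against as the main source of the spread, because the list means differed between uncontrolled and controlled disease by -0.048 SD (95% interval -0.343 to 0.247, permutation p = 0.764) and 0.0454 SD (-0.25 to 0.34, p = 0.766). Blood counts, time from draw to centrifugation, lysis of blood cells in the tube and differences between libraries beyond these measures were not analysed here and stay open.

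The 3 genes that differed between disease states exceeded what regrouping gave: of 100 splits of the samples within batches, 1, the real one, gave 3 genes, and the highest of the others gave 2. The count is rare under regrouping, but this does not exclude chance. It is small, fell to 0 with batch 1 or batch 2 left out, and patients who gave several samples would upset the regrouping. The wider set did not stand out. The 867 genes at an unadjusted p below 0.05 were matched by 40 of 100 splits including the real one (highest 1387), the 8525 windows at an unadjusted p below 0.05 by 9 of 50 (highest 9403), and the area under the curve of 0.522 by 39 labellings, the real one included, when labels were permuted 100 times (highest 0.626). For the gene lists the regroupings decide nothing, since every split has at least the 0 lists observed (100 of 100, highest 3). With background pileup and peak width as covariates, the 3 differences kept a median of 0.959 of their size. That was the outcome predicted if these were not the cause. The prediction was written after the results were seen and so carries no weight. Depth also cannot be argued against here, because the fit already held the spline of peak number. Without that spline the difference was 0.37 for EIF2B1, 0.39 for RNF207 and -0.18 for FBXO16. With the covariates 2 of the 3 calls ended (limma adjusted p = 0.0882 for RNF207 and FBXO16). Weak peaks near the calling threshold could contribute and cannot be told apart, since with peaks of q at most 1e-04 the median ratio was 0.699 and fewer peaks also shrink the scale. All 3 calls ended there: EIF2B1 fell from 0.32 to 0.22 (adjusted p = 0.243), RNF207 from 0.31 to 0.12 (0.757), the largest loss, and FBXO16 moved from -0.35 to -0.28 (0.267). An effect of disease state in these 3 genes stays a hypothesis, without other samples to test it on.

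Whether depth accounts for the wider peaks in uncontrolled disease cannot be told apart here, because the 2 stand-ins for depth go different ways. Of 12.1 bp, the difference in median width was 1.7 bp (SE 4.55) given the background pileup and 10.6 bp (SE 5.48, p = 0.0552) given the log10 peak number. The prediction for the pileup alone was met, but it was written after the results were seen and so carries no weight. The second measure keeps the question open. The higher background pileup could come from batch 2 alone or from several batches. Without batch 2 the log10 difference was 0.0471 (SE 0.0319), against 0.0802 with it, which decides neither. An effect of disease state itself on width or pileup was not tested apart from these and stays open.

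If uncontrolled disease shed more aneuploid tumour DNA, its peak shares would be expected to spread more over the genome. Over 280 bins of 10 Mb, the geometric mean of the spread of log2 shares was 0.143 in uncontrolled and 0.16 in controlled samples. After its own adjustment for batch and peak number the ratio of uncontrolled to controlled turned to 1.06 (95% interval 0.986 to 1.14, permutation p = 0.119). In the 253 samples with at least 10000 peaks the means were 0.118 and 0.125 and the adjusted ratio 1.07 (0.98 to 1.16, p = 0.146). The test leaves that explanation open in either direction.

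Among genes of at least 20 kb, the highest peak densities over all samples belonged to DDX11 (40.5 ± 75.7 peaks per 100 kb per 100000 autosomal peaks, SD, n = 302), DTX2 (33.4 ± 59.2) and ACTR3B (27.6 ± 42.2), genes with near-identical copies elsewhere in the genome, where the position of reads is uncertain. The same holds for RHD and RHCE in the erythroid list.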
